A study of Homo sapiens with 4 samples.

How the data were processed

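RNA from A549 cells was sequenced in 4 libraries, 2 of control and 2 of glutamine-deprived cells. Per the labels' protocols, mRNA was purified from total RNA on poly-T beads, fragmented, copied with random hexamers and amplified by PCR. Per the submitters' processing notes, the reads were handled with HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 on the build hg38 (GRCh38), with no role given for each. The tool that divided reads among transcripts and the annotation release are not given in the sources used here.

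The per-sample files hold 1 value per transcript for 229420 transcripts, which the authors deposited as counts per the file headers. These deposited values are whole numbers but act as estimated counts: in 1756 of 5942 pairs (29.6%) in which a transcript covers every exon of another transcript with at least 100 counts in control replicate 1, the covering transcript had fewer counts. They were therefore treated as estimated counts, already whole, and were summed to genes. GENCODE release 29 (GRCh38) matched 205306 transcript IDs, which held 98.0% to 98.2% of the counts of each library. The 24114 IDs with no match were left out of the genes, so the sum of some genes is partial. Symbols were taken from a table of current gene names, and older symbols from RefSeq synonyms. All 207 loci of the deposited table whose gene is in the annotation overlapped that gene. The deposited table of the series gives FPKM per group, log2 fold changes, a test score and p-values and q-values, all computed by the authors, for 219 long non-coding RNA transcripts. The column names of this table, per the file headers, are those of a pooled group comparison with 1 FPKM per group, and its highest q is 0.0499 and its smallest absolute log2 fold change 1.00.

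Library totals ran from 101496318 to 123414592 counts. Genes were filtered with filterByExpr by group, scaled with TMM (factors 1.15, 1.10, 0.862 and 0.919 for control 1, control 2, deprived 1 and deprived 2) and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The common biological coefficient of variation was 0.210. SEs are the absolute log2 fold change divided by the square root of the quasi-likelihood F. CPM are TMM-scaled unless raw counts are named. Replicates were compared before averaging: the chi-square per degree of freedom was 35.5 between the control and 49.6 between the deprived libraries, so no library was counted as a copy of another. The tests of genes and lists were chosen before the data were examined, for counts per gene; the sum of transcripts to genes was added once the files were seen to hold transcripts.

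Gene lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the 36 lists, all of which had at least 5 tested members. The lists covered the integrated stress response, amino acid synthesis, amino acid transport, aminoacyl-tRNA synthetases, glutamine enzymes, nucleotide synthesis, the TCA cycle, the respiratory chain, mitochondrial mRNAs, glycolysis, hypoxia, endoplasmic reticulum chaperones, heat shock, NRF2, p53, DNA replication, mitosis, ribosome biogenesis, ribosomal proteins, cholesterol, fatty acid synthesis and oxidation, autophagy, NF-kB, interferon, immediate early genes, matrix, epithelial junctions, alveolar type II cells, hexosamine, glutathione, apoptosis, histones, and fibroblast, endothelial and blood markers. Of these, 12 were called higher and 9 lower. None was called with a correlation estimated from the data, where the lowest camera adjusted p was 0.5004. That setting tests on the few residual degrees of freedom of these libraries, so hardly any list can pass it. The estimate was near the preset for p53 targets (0.0126) and matrix genes (0.0094), yet both had a camera adjusted p of 0.5004. The lost calls thus do not by themselves show correlation between genes as the cause. For other called lists the estimate was far above the preset. It was 0.817 for ribosomal proteins, 0.791 for mitochondrial mRNAs, 0.575 for mitosis genes and 0.511 for immediate early genes. Camera's p at the preset can therefore be too small for such lists. H3C2 and H3C3 had no entry in the annotation used.

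The genes named were the 12 largest increases and 12 largest decreases among protein-coding genes with an adjusted p under 0.05, at least 10 CPM on average and both deprived libraries on the same side of both controls; up to 4 genes of each list with the smallest p; and 13 genes fixed in advance, among them GLUL, SLC1A5, SLC38A2, SLC7A11, ASNS, ATF4, DDIT3, TRIB3, CHAC1, PSAT1, CDKN1A and MYC. Some genes that the rule takes are not reported here. SFTPD, PECAM1, CLDN5 and CDH5, also taken by the rule, had under 1 CPM in all libraries, and their changes are not described.

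Alternatives were RLE and upper-quartile factors, library size only, no filter and a filter of at least 50 counts in at least 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, protein-coding genes only, a 2-fold minimum, and for the lists an estimated correlation and fry. Summing only transcripts of protein-coding type, and adding unmatched transcripts that the deposited table pairs with a gene, were chosen after seeing the data. The edgeR step was tested on simulated counts for 23741 genes of this comparison, 2 libraries against 2, with a dispersion of 0.02. That is a smaller spread than that measured here, so recovery in these data can be lower. edgeR recovered 28.4% of 67 genes changed 1.5-fold, 88.1% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 6 false calls among 150. Few simulated genes were changed, in both directions, whereas 49.6% of tested genes were called here. Neither the recovery nor the false calls therefore test the scaling of these libraries. Camera called 3 of 3 changed lists and 0 others among 30 simulated lists over 23745 genes. The simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.85 (histone genes). The simulation therefore does not measure how often camera calls a list falsely in these data. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.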

Results

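RNA sequencing measured gene expression in A549, a human lung adenocarcinoma cell line of alveolar epithelial origin, grown in complete medium or deprived of glutamine. The 4 libraries were 2 of untreated control cells and 2 of deprived cells. The sample labels give 24 hours of deprivation for deprived replicate 1 and 25 hours for deprived replicate 2, whereas the protocol gives 24 hours for both. The deprived cells were washed and given new medium, and the labels of the control cells name no treatment. The files held estimated counts per transcript, which summed to 101496318 and 101982373 in control replicates 1 and 2 and to 123414592 and 120425759 in deprived replicates 1 and 2. At least 1 count fell on 34366 and 32384 genes in the control libraries and on 30681 and 31291 in the deprived libraries. Replicates correlated at r = 0.982 (control) and r = 0.979 (deprived) across genes in log2 CPM, against 0.928 to 0.931 between groups, although genes are not independent replicates. The first principal component held 76.4% of the variance. Expression is given below as mean CPM ± SD over the 2 libraries of a group, and changes as log2 fold change of deprived over control cells ± SE.

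The comparison asked how gene expression in A549 cells differs after a day without glutamine. Deprived cells had more RNA of ATF3 and CDKN1A and less of CDC6 and LSS. ATF3, a stress-induced transcription factor, went from 1.61 ± 0.0279 to 158 ± 14.2 CPM (log2 fold change 6.62 ± 0.11). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, went from 149 ± 2.92 to 1751 ± 115 CPM (3.56 ± 0.10). CDC6, which loads the replicative helicase, went from 114 ± 0.0917 to 13.4 ± 1.01 CPM (-3.09 ± 0.08), and LSS, the lanosterol synthase of cholesterol synthesis, from 103 ± 0.184 to 12.2 ± 0.590 CPM (-3.07 ± 0.08). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6174 of 24527 tested genes were higher and 5982 were lower in deprived cells at an adjusted p under 0.05, 49.6% of all tested. With a change of at least 2-fold, 3030 were higher and 3754 lower. Among 15411 protein-coding genes, 5290 were higher and 4592 lower, and among 5506 long non-coding RNA genes, 551 were higher and 958 lower. Higher genes made up 50.8% of the calls with TMM scaling and 32.8% (4179 higher, 8565 lower) with library size only, which moved the median log2 fold change of all genes from -0.06 to -0.40. Upper-quartile factors moved it to -0.17, so all changes below are relative to TMM scaling.

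**Figure D1:**
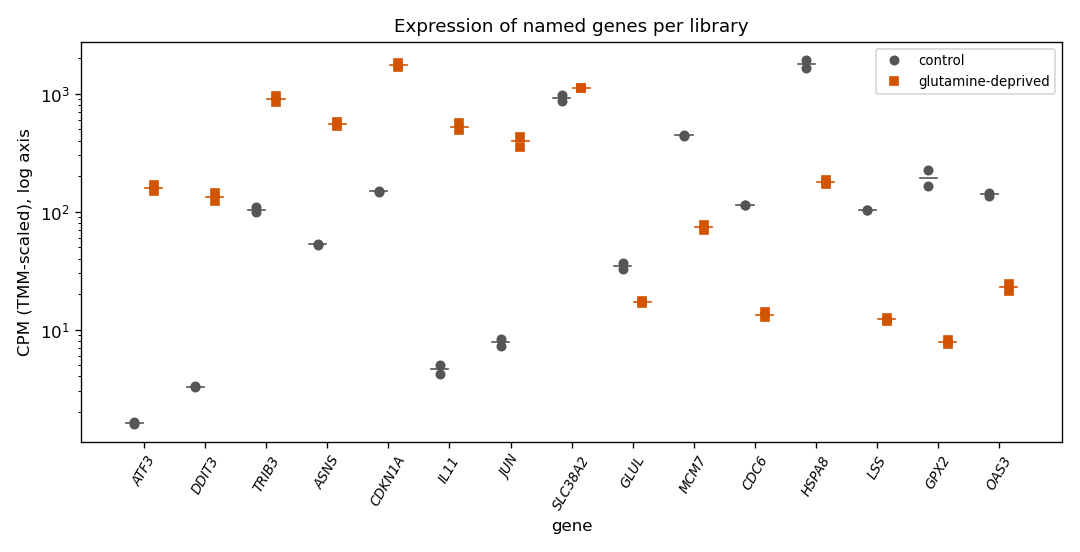
CPM (TMM-scaled, log axis) of 15 named genes in each library, with control libraries as circles, glutamine-deprived libraries as squares and group means as lines (n = 2 per group). ATF3 rose from 1.61 to 158 CPM and JUN from 7.76 to 393 CPM, whereas LSS fell from 103 to 12.2 CPM.

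The 12 largest increases among protein-coding genes of at least 10 CPM included a cytokine, several transcription factors and a pair of arrestin-domain genes. IL11, an interleukin of the IL-6 family (ENSG00000095752), went from 4.59 ± 0.531 to 525 ± 53.7 CPM (6.84 ± 0.14, edgeR adjusted p = 8.64e-06). TXNIP and ARRDC4, arrestin-family regulators of glucose uptake, went from 0.826 ± 0.565 to 92.3 ± 8.77 CPM and from 0.531 ± 0.276 to 41.7 ± 0.971 CPM. The transcription factor genes CREB5 (6.80 ± 0.14), EGR1 (6.77 ± 0.55), ATF3 and MAFF (6.47 ± 0.13) were among the 12, as were the reductase gene DHRS2 (6.74 ± 0.12), NIBAN1 (6.25 ± 0.09), the neuropeptide precursor gene VGF (5.94 ± 0.30) and ANKRD1 (5.90 ± 0.23), an ankyrin repeat gene induced by YAP. The largest, TMEM265 (9.67 ± 0.36), shares exons with other annotated genes on its strand, so its value is uncertain.

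The 12 largest decreases covered epithelial, antioxidant and interferon-induced genes. CLDN2, a tight junction claudin, fell from 66.6 ± 0.599 to 2.34 ± 0.189 CPM (-4.83 ± 0.10), the epithelial transcription factor gene EHF from 45.7 ± 0.953 to 1.85 ± 0.123 CPM, and the glutathione peroxidase gene GPX2 from 194 ± 41.9 to 7.80 ± 0.404 CPM. CPLX2, a complexin of vesicle fusion, fell from 617 ± 25.2 to 29.4 ± 3.35 CPM. Other decreases among the 12 were those of FAM111B (-5.48 ± 0.12), NFIA (-5.38 ± 0.50), the antiviral gene OAS1 (-4.87 ± 0.25), LRRC45 (-4.84 ± 0.18), C11orf86 (-4.41 ± 0.12), the ferritin receptor gene SCARA5 (-4.17 ± 0.15) and ENSG00000257524 (-5.57 ± 0.89). The last is annotated across exons of AK1 and ST6GALNAC6, and LRRC45 overlaps CENPX on the other strand, so reads of these genes cannot be told apart with certainty.

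Genes of the integrated stress response, the program that ATF4 drives when amino acids run short, rose together. Of 24 tested, 18 rose and 3 fell, with a median log2 fold change of 1.96 (camera adjusted p = 1.86e-06, and camera adjusted p = 0.5004 with an estimated correlation). Here and below, the estimated setting rests on few residual degrees of freedom, so its adjusted p does not show that correlation undoes a call. Nor does it show that a call stands, as the estimated correlation was far above the preset for several lists. DDIT3 (CHOP; chromosome 12, 57516588 to 57521737) went from 3.28 ± 0.0276 to 133 ± 13.2 CPM, PPP1R15A (GADD34) from 13.6 ± 0.683 to 518 ± 67.4 CPM, and TRIB3 from 104 ± 7.23 to 903 ± 66.4 CPM (chromosome 20, 362835 to 397559). ATF4 itself rose by 1.86 ± 0.24, with 409 and 670 CPM in the deprived libraries against 165 and 132 in the controls, and STC2 and CHAC1 rose by 3.69 ± 0.10 and 2.67 ± 0.13. Of 22 amino acid synthesis enzymes, 13 rose and 6 fell (median 0.60; camera adjusted p = 0.0112; adjusted p = 0.653 with an estimated correlation), against 10 and 7 with library size only (median 0.27). ASNS, which makes asparagine from aspartate with glutamine nitrogen, rose from 53.01 ± 0.665 to 554 ± 34.6 CPM (3.39 ± 0.09), and ALDH1L2 (3.06 ± 0.08) and BCAT1 (2.39 ± 0.07) also rose. PSAT1 rose by 0.54 ± 0.08, a call lost with library size only (adjusted p = 0.0770), and SHMT1 fell by 2.60 on the log2 scale. Of 20 cytosolic aminoacyl-tRNA synthetases, 13 rose and 3 fell (median 1.12; camera adjusted p = 0.000201; adjusted p = 0.5004 with an estimated correlation). MARS1 (2.18 ± 0.10), SARS1 (2.15 ± 0.09), CARS1 (2.04 ± 0.07) and GARS1 (1.85 ± 0.08) had the smallest p, and GARS1 turned to -2.72 (adjusted p = 0.155) when only its transcripts of protein-coding type were summed. Adjusted over the list alone, 18 stress response genes rose and 3 fell, 14 synthesis enzymes rose and 6 fell, and 15 synthetases rose and 3 fell. DDIT3 and MARS1 overlap on opposite strands.

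Genes that use, make or carry glutamine went both ways. Of 19 glutamine-using and glutamine-making enzymes, 6 rose and 9 fell (camera adjusted p = 0.866). The median was -0.26 and camera's direction down, whereas the mean was 0.11 and fry's direction up (fry adjusted p = 0.0123). CTPS1, which makes CTP with glutamine nitrogen, rose from 85.0 ± 3.25 to 522 ± 18.3 CPM. GFPT1, the first enzyme of the hexosamine pathway, rose by 1.03 ± 0.07. GLUL, the glutamine synthetase gene (chromosome 1, 182381704 to 182392206), fell from 34.8 ± 2.79 to 17.01 ± 0.493 CPM (-1.03 ± 0.09, edgeR adjusted p = 0.000244). Of 22 amino acid transporters, 10 rose and 6 fell (camera adjusted p = 0.144, but fry adjusted p = 0.00291, direction up). With library size only 7 rose and 8 fell, the median of 0.31 turning to -0.02. SLC7A1 (2.82 ± 0.09), SLC7A6 (1.60 ± 0.07) and SLC38A1 (1.51 ± 0.08) rose and SLC7A7 fell (-3.01 ± 0.18). The cystine carrier gene SLC7A11 fell from 785 ± 11.4 to 521 ± 15.4 CPM. The glutamine carrier gene SLC1A5 rose by 0.52 ± 0.09, a call lost with library size only (0.18, adjusted p = 0.146), and SLC38A2 was at 922 ± 75.1 and 1118 ± 8.49 CPM, not called by edgeR (adjusted p = 0.0525) but called higher by DESeq2, limma-voom and RLE scaling (adjusted p = 0.00243, 0.0181 and 0.0435) and at -0.05 with library size only. Of 24 purine and pyrimidine synthesis genes, 7 rose and 12 fell (camera adjusted p = 0.233, but 0.0138 with library size only, where 2 rose and 15 fell), 3 rising without control replicate 1, with PRPS2 (-1.94 ± 0.09), IMPDH1 (-1.05 ± 0.07) and DTYMK (-0.85 ± 0.07) lower. Of 14 hexosamine and N-glycan precursor genes, 7 rose and 4 fell (camera adjusted p = 0.526), with a median of 0.13 that turned to -0.20 with library size only (4 rose, 7 fell), among them OGA (1.14 ± 0.08), GNPNAT1 (0.85 ± 0.07) and MGAT5 (-2.21 ± 0.08). With p adjusted over the list alone, 6 glutamine enzymes rose and 10 fell, 11 transporters rose and 6 fell, 7 nucleotide genes rose and 12 fell, and 7 hexosamine genes rose and 5 fell.

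**Figure D2:**
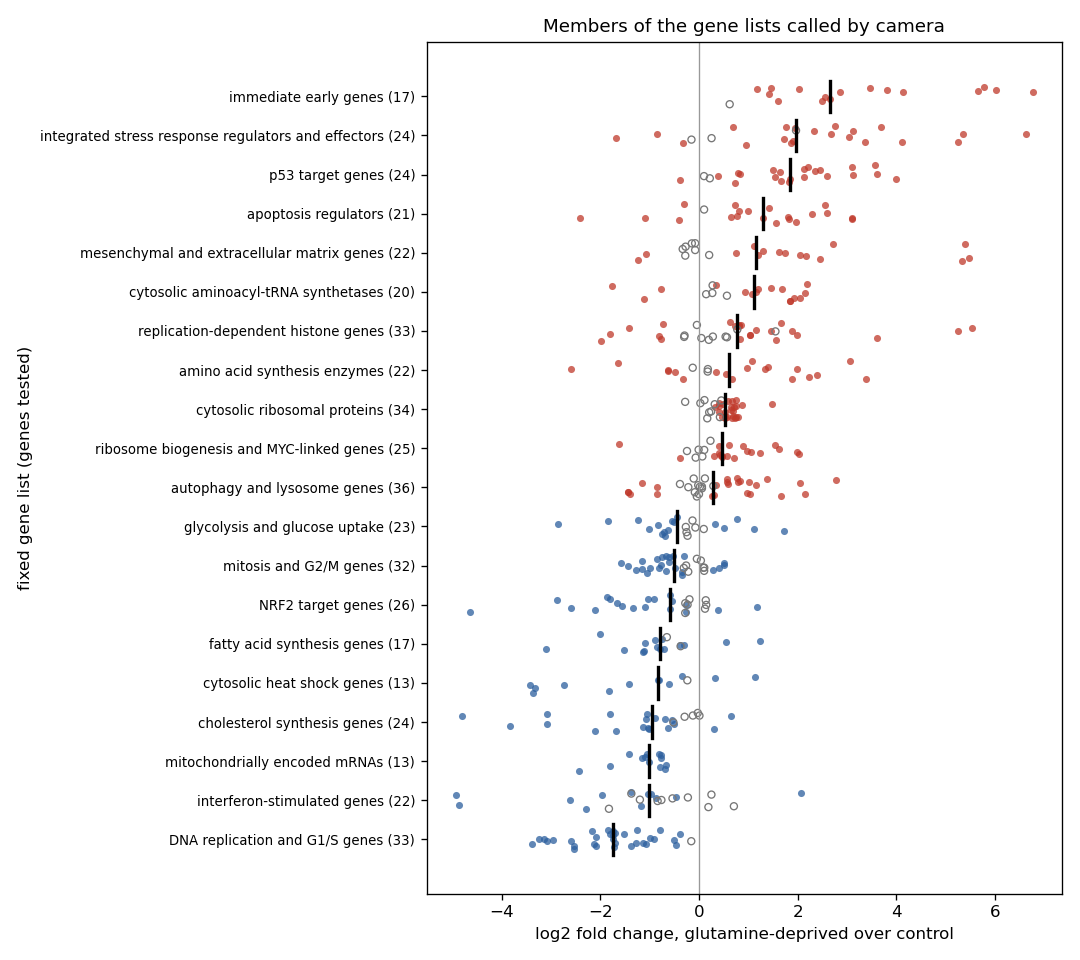
Log2 fold change (glutamine-deprived over control, TMM scaling) of every tested member of 20 gene lists called by camera, with filled points for genes past an edgeR adjusted p of 0.05, open points for the rest and black lines for list medians. The list medians run from -1.74 (DNA replication and G1/S genes) to 2.64 (immediate early genes). The NF-kB list, also called, is not drawn, because its member IL6 lacked counts in every library of a group.

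DNA replication genes fell and p53 target genes rose. Of 33 DNA replication and G1/S genes, 32 fell and 0 rose (median -1.74; camera adjusted p = 6.60e-15; adjusted p = 0.5004 with an estimated correlation). The helicase subunit gene MCM7 fell from 443 ± 2.24 to 73.6 ± 5.13 CPM (-2.59 ± 0.08), the polymerase delta gene POLD1 from 160 ± 10.5 to 20.7 ± 0.348 CPM and GINS2 by 3.25 on the log2 scale. Of 32 mitosis and G2/M genes, 20 fell and 4 rose (median -0.51; camera adjusted p = 0.000433; adjusted p = 0.638 with an estimated correlation), against 27 and 0 with library size only. KIF20A (-1.58 ± 0.11), ASPM (-1.44 ± 0.07), CDC20 (-1.27 ± 0.10) and PLK1 (-1.15 ± 0.08) fell. Of 24 p53 target genes, 21 rose and 1 fell (median 1.84; camera adjusted p = 7.44e-11; adjusted p = 0.5004 with an estimated correlation). Besides CDKN1A (chromosome 6, 36676460 to 36687339), BTG2 rose from 16.3 ± 0.602 to 199 ± 9.45 CPM, AEN from 193 ± 7.73 to 1686 ± 156 CPM and the death receptor gene TNFRSF10B from 280.0 ± 4.44 to 1690 ± 60.1 CPM. Of 21 apoptosis regulators, 16 rose and 4 fell (median 1.29; camera adjusted p = 5.44e-05; adjusted p = 0.5004 with an estimated correlation). The risers with the smallest p opposed each other in known function: BIRC3 (3.10 ± 0.07) and MCL1 (2.30 ± 0.08) restrain cell death, whereas PMAIP1 (2.55 ± 0.08) and TNFRSF10B promote it. Of 33 replication-dependent histone genes, 17 rose and 6 fell (median 0.78; camera adjusted p = 0.0190; adjusted p = 0.736 with an estimated correlation). H4C3 rose from 99.0 ± 18.4 to 391.6 ± 64.3 CPM and H1-5 fell from 70.8 ± 6.75 to 17.9 ± 2.54 CPM, while H2AC8 and H3C4 rose from 0.0851 to 3.98 and from 0.217 to 8.30 CPM. Most mRNAs of these genes lack a poly(A) tail, and the libraries were described as poly-T selected. These counts may therefore not follow total histone mRNA. Other RNAs that lack a tail nonetheless took 3.14% to 4.38% of counts, so how far the selection applied is unclear. The histone call was lost without deprived replicate 1 (adjusted p = 0.0753) and by fry (adjusted p = 0.199), and histone genes are near-identical copies. The counts adjusted over the list alone were close: 32 replication genes fell, 21 mitosis genes fell and 4 rose, 22 p53 targets rose and 1 fell, 16 apoptosis genes rose and 4 fell, and 19 histone genes rose and 6 fell.

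Genes of sterol and fatty acid synthesis fell. Of 24 cholesterol synthesis genes, 17 fell and 2 rose (median -0.96; camera adjusted p = 4.79e-06; adjusted p = 0.5004 with an estimated correlation). Besides LSS, INSIG1 fell from 144 ± 8.23 to 17.1 ± 1.78 CPM and DHCR7 from 102 ± 1.30 to 23.6 ± 0.434 CPM. Of 17 fatty acid synthesis genes, 13 fell and 2 rose (median -0.80; camera adjusted p = 0.000276; adjusted p = 0.5004 with an estimated correlation). The desaturase genes SCD and FADS2 fell from 3315 ± 261 to 827 ± 16.4 CPM and from 701 ± 34.1 to 82.1 ± 9.88 CPM, FASN fell by 1.51 on the log2 scale and LPIN1 rose by 1.24 ± 0.08. Of 17 fatty acid oxidation genes, 3 rose and 8 fell (camera adjusted p = 0.0804, but 0.00720 with library size only, where 1 rose and 12 fell), with PPARA (-1.27 ± 0.15) and ACADS (-0.88 ± 0.09) lower. Fry called this list lower (fry adjusted p = 0.00715). HADH was lower by 2.40 on the log2 scale but at 0.61 (adjusted p = 0.0522) when only transcripts of protein-coding type were summed. Adjusted over the list alone, 19 cholesterol genes fell and 2 rose, 13 fatty acid synthesis genes fell and 2 rose, and 3 oxidation genes rose and 10 fell.

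Antioxidant and heat shock genes fell as well. Of 26 NRF2 target genes, 17 fell and 2 rose (median -0.59; camera adjusted p = 2.90e-05; adjusted p = 0.5004 with an estimated correlation). PGD, of the pentose phosphate pathway, fell from 1337 ± 107 to 221 ± 26.7 CPM, the haem oxygenase gene HMOX1 from 190 ± 4.45 to 43.9 ± 3.69 CPM and AKR1C1, which has close paralogs, from 2273 ± 275 to 310 ± 15.2 CPM. Of 20 glutathione metabolism genes, 3 rose and 9 fell (camera adjusted p = 0.0725, but fry adjusted p = 0.0410, direction down). GCLM (-1.57 ± 0.08) and GCLC (-1.09 ± 0.07), the subunits of the rate-limiting enzyme of glutathione synthesis, were lower. The glutathione list passed the threshold without control replicate 1 (adjusted p = 0.0175), without deprived replicate 1 (adjusted p = 0.0312) and with library size only (adjusted p = 0.0238; 1 rose, 12 fell). Of 13 cytosolic heat shock genes, 10 fell and 2 rose (median -0.84; camera adjusted p = 0.000239; adjusted p = 0.5004 with an estimated correlation). The constitutive chaperone gene HSPA8 fell from 1792 ± 186 to 178 ± 9.39 CPM and HSP90AA1 from 1073 ± 21.2 to 302 ± 1.70 CPM. HSPA1A (-3.42 ± 0.07) and HSPA1B (-3.37 ± 0.07) are near-identical, so their separate values are uncertain. Of 24 endoplasmic reticulum chaperone and unfolded protein response genes, 9 rose and 8 fell (camera adjusted p = 0.789), with a median of -0.04 although camera's direction was up; with library size only 5 rose and 10 fell (median -0.37). HSPA5 (BiP) rose from 209 ± 10.1 to 438 ± 2.40 CPM and HERPUD1 by 0.96 ± 0.07, whereas CALR (-1.15 ± 0.10) and PDIA4 (-1.11 ± 0.07) fell. When adjusted over the list alone, 17 NRF2 targets fell and 2 rose, 3 glutathione genes rose and 9 fell, 11 heat shock genes fell and 2 rose, and 9 chaperone genes rose and 8 fell.

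Mitochondrially encoded mRNAs, also a check of RNA composition, were lower in deprived cells. All 13 fell (median -1.01; camera adjusted p = 0.000112; adjusted p = 0.552 with an estimated correlation). Together they held 0.446% and 0.390% of counts in the control libraries and 0.195% and 0.184% in the deprived libraries. MT-ND6 (-2.44 ± 0.15), MT-ND5 (-1.80 ± 0.13), MT-ND3 (-1.42 ± 0.15) and MT-CO3 (-0.76 ± 0.09) had the smallest p. Of 28 nuclear-encoded respiratory chain subunits, 9 rose and 5 fell (camera adjusted p = 0.218), with UQCRFS1 (1.15 ± 0.10), ATP5PB (0.83 ± 0.09) and COX5A (0.73 ± 0.08) higher and UQCRB (-0.81 ± 0.09) lower. This list, with a median of 0.22 that turned to -0.11 with library size only (5 rose, 11 fell), passed the threshold without deprived replicate 2 (14 rose, 5 fell; adjusted p = 0.0354). Of 26 TCA cycle enzymes, 9 rose and 5 fell (camera adjusted p = 0.922), against 2 and 16 with library size only, SDHD (1.26 ± 0.11) rising and IDH2 (-1.56 ± 0.11), PC (-1.46 ± 0.10) and IDH1 (-0.85 ± 0.08) falling. Of 23 glycolysis and glucose uptake genes, 12 fell and 5 rose (median -0.45; camera adjusted p = 0.0214; adjusted p = 0.5004 with an estimated correlation), against 17 and 2 with library size only. ALDOC (-2.86 ± 0.21), the lactate exporter gene SLC16A3 (-1.84 ± 0.08) and PFKFB3 (-1.23 ± 0.08) fell, and PFKP rose by 1.72 ± 0.07. Of 18 hypoxia-induced genes, 7 rose and 7 fell (camera adjusted p = 0.729), with a median of 0.22 that turned to -0.11 with library size only (5 rose, 8 fell) and a mean of -0.34. ADM rose from 26.2 ± 4.76 to 584 ± 59.2 CPM, EGLN1 by 1.21 ± 0.08 and KDM3A by 1.23 ± 0.07, and EGLN3 fell (-3.16 ± 0.12). The counts of these lists adjusted over the list alone were the same.

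Immediate early genes, inflammatory cytokine genes and matrix genes rose. Of 17 immediate early genes, 16 rose (median 2.64; camera adjusted p = 1.17e-09; adjusted p = 0.5004 with an estimated correlation). JUN went from 7.76 ± 0.733 to 393 ± 52.3 CPM (5.66 ± 0.14), the phosphatase gene DUSP1 from 165 ± 5.39 to 2312 ± 177 CPM, and FOSL1 and KLF6 rose by 5.77 ± 0.14 and 2.55 ± 0.07. Of 23 NF-kB targets and inflammatory cytokines, 13 rose and 3 fell (median 0.55; camera adjusted p = 0.00493; adjusted p = 0.5004 with an estimated correlation), against 10 and 7 with library size only (median 0.21). Besides IL11, the chemokine gene CXCL8 rose from 3.91 ± 0.0066 to 182 ± 17.7 CPM and TNFAIP3 by 3.05 ± 0.09. Of 22 mesenchymal and extracellular matrix genes, 13 rose and 2 fell (median 1.15; camera adjusted p = 0.00102; adjusted p = 0.5004 with an estimated correlation). CCN2, a matricellular growth factor gene, rose by 5.33 ± 0.16, and the collagen genes COL4A1 and COL5A1 rose by 2.45 ± 0.07 and 2.04 ± 0.07. Adjusted over the list alone, 17 immediate early genes rose, 13 NF-kB targets rose and 4 fell, and 14 matrix genes rose and 3 fell.

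Interferon-stimulated genes fell, and epithelial and alveolar genes went both ways. Of 22 interferon-stimulated genes, 11 fell and 1 rose (median -1.01; camera adjusted p = 0.00493; adjusted p = 0.540 with an estimated correlation). OAS3 fell from 140 ± 6.81 to 22.8 ± 2.10 CPM and IFIT1 by 4.93 on the log2 scale, and ISG20 rose by 2.07 ± 0.09. Of 17 epithelial junction and keratin genes, 6 rose and 9 fell (median -1.13; camera adjusted p = 0.475). Claudins moved in opposite directions, CLDN1 from 56.1 ± 0.978 to 1039 ± 50.1 CPM and CLDN2 downward, while OCLN rose by 1.91 ± 0.07 and JUP fell (-2.26 ± 0.08). Of 9 alveolar type II cell genes, 2 rose and 4 fell (camera adjusted p = 0.245, but fry adjusted p = 0.0210, direction down). LPCAT1 (-1.17 ± 0.08) and the lipid transporter gene ABCA3 (-0.55 ± 0.07) fell. NKX2-1 was called higher, from 0.0405 to 0.793 CPM, but stayed under 1 CPM in all 4 libraries. The counts of this list thus rest in part on genes near the floor. Adjusted over the list alone, 11 interferon genes fell and 1 rose, 6 epithelial genes rose and 10 fell, and 2 alveolar genes rose and 4 fell.

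Ribosomal protein, ribosome biogenesis and autophagy genes rose by smaller amounts. Of 34 cytosolic ribosomal protein genes, 25 rose and 0 fell (median 0.53; camera adjusted p = 1.01e-05; adjusted p = 0.635 with an estimated correlation), though fry did not call the list (adjusted p = 0.111) and 14 genes rose without control replicate 1 and 11 with library size only. RPS27 (1.49 ± 0.17), RPS9 (0.88 ± 0.12), RPL5 (0.76 ± 0.10) and RPL37 (0.70 ± 0.07) had the smallest p, RPS9 lost its call with protein-coding transcripts only (adjusted p = 0.0549), and this family shares reads with many pseudogenes. Of 25 ribosome biogenesis and MYC-linked genes, 17 rose and 2 fell (median 0.47; camera adjusted p = 0.000276; adjusted p = 0.540 with an estimated correlation), against 11 and 5 with library size only (median 0.13). MYC rose from 59.4 ± 1.42 to 241 ± 32.7 CPM, the helicase gene DDX21 from 182 ± 6.08 to 719 ± 28.8 CPM, and NIP7 and RRP12 by 1.62 ± 0.07 and 1.53 ± 0.07. Of 36 autophagy and lysosome genes, 18 rose and 6 fell (median 0.28; camera adjusted p = 0.0316; adjusted p = 0.559 with an estimated correlation), but with library size only 14 rose and 16 fell (median -0.06; adjusted p = 0.266). The autophagy call was also lost without deprived replicate 1 (adjusted p = 0.0556) and with the stricter filter (adjusted p = 0.136). MAP1LC3B, which encodes the autophagosome protein LC3B, rose from 52.2 ± 2.87 to 360 ± 2.06 CPM, NBR1 by 2.14 ± 0.07, GABARAPL1 by 2.05 ± 0.09 and FNIP1 by 1.39 ± 0.07. With p-values adjusted over the list alone, 26 ribosomal protein genes rose, 17 biogenesis genes rose and 2 fell, and 18 autophagy genes rose and 6 fell.

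The tested markers of fibroblasts, endothelial cells and blood cells each averaged under 30 CPM in both groups. Of 6 fibroblast markers, 2 fell and 0 rose (camera adjusted p = 0.180), THY1 from 10.1 ± 0.203 to 2.52 ± 0.201 CPM and PDGFRA from 1.30 ± 0.330 to 0.508 ± 0.0802 CPM, the latter lost without control replicate 2 (adjusted p = 0.105). Of 5 endothelial markers, 1 rose and 3 fell (camera adjusted p = 0.488) but 0 fell without either control library, ESAM rising from 6.84 ± 1.04 to 26.3 ± 3.70 CPM. Of 7 blood cell markers, 0 rose and 3 fell (camera adjusted p = 0.246), and the list passed the threshold without control replicate 2 (5 fell; adjusted p = 0.00200), whereas without control replicate 1 there were 1 that rose and 1 that fell. CD14 fell from 12.8 ± 0.597 to 0.512 ± 0.0194 CPM. The haemoglobin gene HBB had 1326 counts in control replicate 1 and 25, 14 and 12 in control replicate 2 and deprived replicates 1 and 2, and LYZ had 147, 12, 0 and 6. Without control replicate 1 the HBB and LYZ calls were lost (adjusted p = 0.494 and 0.452). Adjusted over the list alone, 2 fibroblast markers fell, 1 endothelial marker rose and 3 fell, and 5 blood markers fell. Fry called the fibroblast list lower (fry adjusted p = 0.0210).

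The authors' deposited table lists long non-coding RNA transcripts that differ between the groups, and host genes of small nucleolar RNAs lead its increases. It holds 219 transcripts of 193 genes, 103 higher and 116 lower in deprived cells. SNHG1-211 went from 15.0 to 403 FPKM and CYTOR-201 from 74.4 to 731 FPKM in the authors' deposited table, and IGFL2-AS1-210 fell from 22.3 to 1.37 FPKM. SNHG1-211 had only 10, 11, 30 and 43 counts in control replicates 1 and 2 and deprived replicates 1 and 2. It was not called by edgeR on single transcripts (adjusted p = 0.119), so its FPKM in that table do not match the counts. In the authors' deposited table, 15 transcripts of 9 genes named SNHG were higher and 0 lower. These transcripts were chosen for naming after their values were seen. Among them, SNHG8-206 had fewer counts in deprived replicates 1 and 2 (340 and 368) than in control replicates 1 and 2 (467 and 699). By edgeR on genes, SNHG17 was not called (adjusted p = 0.111). Summed to genes, 175 of the 193 genes were tested and 161 were called by edgeR, all 161 with the sign of the authors' deposited table. SNHG1 rose by 5.13, CYTOR by 3.36 and GAS5 by 3.19, and IGFL2-AS1 fell by 3.72 on the log2 scale. At the transcript level 211 of 214 tested transcripts had the sign of the authors' deposited table, with 15 called by edgeR. The authors' deposited table comes from the same libraries and is not independent evidence.

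With 2 libraries per group, p-values measure the spread between these libraries, which the labels do not describe as separate cultures. The SLC1A5 value is uncertain, as its exons overlap other annotated genes. Several named genes overlap a gene on the other strand (FADS2 and FADS1, MCM7 and AP4M1, GINS2 and GSE1, TNFRSF10B and RHOBTB2, KIF20A and CDC23, SHMT1 and SMCR8, PC and LRFN4, SLC16A3 and CSNK1D, MAP1LC3B and FBXO31, HSP90AA1 and WDR20, ALDH1L2 and C12orf45, ATP5PB and WDR77, SDHD and TIMM8B, NIP7 and COG8, SLC7A6 and SLC7A6OS) or one on the same strand (ASNS and AC079781.5, FADS2 and FEN1, GCLC and AL033397.1, MCL1 and ADAMTSL4-AS1, H3C4 and AL031777.3, MT-CO3 and MT-ATP6), and no source used here states that strand was used in counting.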

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

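The test on transcripts outside the annotation was chosen after the data were seen. Among the 24114 transcripts with no match in the annotation, which the gene comparisons leave out, 5056 had enough counts to test and 15 were higher and 7 lower in deprived than in control cells by edgeR on single transcripts. Among matched transcripts, 624 of 83759 were higher and 272 lower. Signal in data outside the main comparison put these 15 transcripts here, and no explanation was tested for them.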

How the results depend on the processing

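The tests on protein-coding transcripts alone and with unmatched transcripts were chosen after the data were seen. The 6174 genes higher ranged from 4179 (library size only) to 6420 (DESeq2) and the 5982 lower from 4543 (without control replicate 1) to 8565 (library size only) over all alternatives but the 2-fold minimum, which by its construction left 3030 and 3754. Leaving out each library gave 5250 to 5981 higher and 4543 to 6040 lower, the lone library of a group being assumed to vary like the other group's. With the replicate block there were 5529 higher and 5079 lower; the labels share only the number, and same-numbered deviations correlated at -0.02 over all tested genes (-0.11 for genes of at least 10 CPM). Of the 12 lists higher and 9 lower, 0 and 0 passed with an estimated correlation, and 10 to 13 higher and 9 to 10 lower passed without each library. Of 163 named genes, 150 kept their direction and side of the threshold in every setting that tested them. GARS1 (-2.72) and HADH (0.61) changed sign with protein-coding transcripts only, and SLC38A2 (-0.0547) with library size only. With library size only the medians of respiratory chain subunits (-0.11), amino acid transporters (-0.02), hexosamine genes (-0.20), hypoxia-induced genes (-0.11) and autophagy genes (-0.06) turned negative, and camera's direction turned for respiratory chain subunits and for endoplasmic reticulum chaperones, whose median in voom values was negative in both scalings (-0.01 and -0.35). For TCA cycle enzymes, not called in any of these, camera's direction turned without control replicate 2 (median 0.0042) and without deprived replicate 2 (-0.0052), the medians without each library running from -0.14 to 0.0042. By fry, the glutamine enzymes (median -0.26) and epithelial genes (median -1.13) had direction up where camera gave down. The cause was not tested. In camera's direction, fry passed 5 lists that camera did not. These were amino acid transporters (up) and fatty acid oxidation genes, alveolar genes, glutathione genes and fibroblast markers (down). The overlap with the authors' deposited table was 161 genes by edgeR and 163 by DESeq2. CDH5, CLDN5 and PECAM1, under 1 CPM in all libraries, lost their calls without either control library. HBB and LYZ lost theirs without control replicate 1, which held most of their counts, without deprived replicate 1, with no filter, with limma-voom and with protein-coding transcripts only.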

Other observations

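All 9 lists of this part, the genes named from them and all tests but that on decay factor genes were chosen after the gene results were seen. YAP and TEAD target genes, which respond to cell shape and density, rose in deprived cells, and homologous recombination and Fanconi anaemia genes fell. Of 22 YAP and TEAD targets, 20 rose and 1 fell (median log2 fold change 2.20; camera adjusted p = 3.11e-11; adjusted p = 0.152 with an estimated correlation): CCN1 went from 2.07 to 91.7 CPM, AMOTL2 from 81.3 to 789 CPM and AXL from 253 to 1384 CPM. Of 22 recombination and Fanconi genes, 20 fell and 1 rose (median -1.42; camera adjusted p = 6.19e-09; adjusted p = 0.283 with an estimated correlation): FANCA went from 63.7 to 10.9 CPM and BLM from 62.6 to 15.6 CPM. Of 17 dual specificity phosphatases, 11 rose and 4 fell (camera adjusted p = 0.0115; adjusted p = 0.367 with an estimated correlation), DUSP6 from 8.82 to 97.1 CPM. Of 13 SR splicing factors, 9 rose and 2 fell, against 6 and 3 with library size only (camera adjusted p = 0.00503; adjusted p = 0.283 with an estimated correlation), TRA2B from 186 to 457 CPM. Of 15 aldehyde dehydrogenases, 7 fell and 0 rose, against 12 and 0 with library size only (camera adjusted p = 0.00503; adjusted p = 0.308 with an estimated correlation), ALDH3A1 from 1296 to 629.6 CPM. Proteasome subunits (15 rose, 6 fell of 31), mitochondrial ribosomal proteins (10 rose, 8 fell of 30) and mitochondrial aminoacyl-tRNA synthetases (3 rose, 7 fell of 17) were not called (camera adjusted p = 0.0896, 0.999 and 0.232); with library size only 8 proteasome subunits rose and 13 fell, the median of 0.28 turning to -0.06, and 3 of the synthetases rose and 10 fell, and for the mitochondrial ribosomal proteins, whose median was -0.07 although camera's direction was up, 7 rose and 17 fell with that scaling (median -0.41).

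Small nucleolar RNA host genes rose on balance. Of 24 tested, 12 rose and 4 fell (median 0.65; camera adjusted p = 0.00973; adjusted p = 0.283 with an estimated correlation), with GAS5 from 47.5 to 433 CPM, SNHG1 from 12.4 to 435 CPM, SNHG15 from 8.93 to 80.5 CPM and ZFAS1 from 33.1 to 176 CPM, while SNHG4 and SNHG14 fell. For the list as a set, the check of scaling decides little. A first criterion on the median with library size only (0.33) decided nothing. By a count chosen in its place, 10 of the 24 were still called higher and 5 lower. Over all genes, 4179 of 24527 were higher with that scaling. The count was close to fixed in advance, since this scaling moved the median log2 fold change of all genes only from -0.06 to -0.40. Rises such as those of SNHG1 (5.13) and GAS5 (3.19) are far larger than this move, which argues against scaling as their whole cause. Many of these RNAs are known targets of nonsense-mediated decay, and less decay is a candidate explanation. In 2051 protein-coding genes the ratio of decay-type to coding transcripts rose by a median of 0.26 on the log2 scale but was higher in only 56.5% of them. The medians of retained-intron (-0.14, 3640 genes) and other processed transcripts (-0.10, 1693 genes) lay within the gap between the deprived replicates. Both were larger in size than the gap between the control replicates (0.11 and 0.08). Of 7 decay factor genes whose own mRNAs are decay targets, among them UPF1 and UPF3B, 7 were higher with TMM, where 34.3% of protein-coding genes were, and 5 with library size only; more transcription of these genes was not tested and stays open.

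Control replicate 1 held blood and a few liver transcripts that the other libraries nearly lacked. Of the 20 blood and 20 liver markers, 13 were at least 5-fold above every other library there, 10 of them blood markers, against 0 in each other library and 0 neuron or muscle markers. The most abundant of the 13 were HBB (13.1 CPM), HBA2 (9.90), HBA1 (8.57) and ALB (3.25), in CPM of the library total, with at most 0.245 CPM in the other libraries; 6 of the liver markers and 0 of the blood markers had at least 20 counts in all 3 other libraries. Counting noise is excluded, since HBB, HBA1 and HBA2 were each at least 44.4-fold above the highest other library, and RNA or reads from another sample may be the source. No biological explanation was tested, and of the 5982 genes lower only 4 had control replicate 1 at least 5-fold above control replicate 2.

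RNAs that lack a poly(A) tail (RN7SL1, RN7SL2, RN7SK, RPPH1 and RMRP) took 3.14% and 4.25% of counts in control replicates 1 and 2 and 4.38% and 3.40% in deprived replicates 1 and 2, in libraries described as poly-T selected. SNHG8-201 is listed at 22.7 and 275 FPKM in the authors' deposited table and at 0 counts in all 4 libraries, and SNHG1-211 at 15.0 and 403 FPKM in that table but at 10, 11, 30 and 43 counts in control replicates 1 and 2 and deprived replicates 1 and 2.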
